A study of Homo sapiens with 6 samples.

How the data were processed

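RNA of SW620 cells was sequenced 72 h after transfection, per the labels' protocols, from poly(A) RNA in a strand-specific library with paired reads of 150 nt, for samples with an RNA integrity number above 7.0. There were 3 siNC and 3 siSOWAHA libraries. Groups and replicate numbers were taken from the sample titles, because the treatment label reads as a knockdown for all 6 samples. Reads were trimmed with cutadapt 1.9, checked with FastQC and set against GRCh38, per the submitters' processing notes. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here.

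The authors deposited raw counts per gene for 39554 Entrez gene IDs, of which 14652 were at 0 in all libraries. A second deposited table held FPKM values of 24901 genes beside the same counts, with identical counts in all 6 libraries for all 24901. In the authors' FPKM values the ratio of count to FPKM of a gene differed between libraries by a single factor per library, with an SD between genes of at most 0.0019 on the log2 scale over 11399 genes. Gene IDs were given RefSeq symbols for 95.9% of IDs, which held 99.91% of counts. In the deposited table of FPKM values, 1582 genes were listed with a copy on an alternate or patch scaffold; these held 5.36% of counts, and no coordinates are printed for them. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 8.09 to 14.8, and were kept as separate samples.

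Counts as deposited were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM factors, robust quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment at 0.05 over the 17693 genes kept. The SE of a log2 fold change was its size over the square root of F. CPM values use TMM factors. Depth was 49937395 to 59474396 counts per library, and the common biological coefficient of variation was 0.105. On counts simulated for 17307 tested genes with 3 against 3 libraries, the steps called 72% of genes changed 1.25-fold, 76% changed 1.5-fold, 94% changed 2-fold and 96% changed 3-fold, and 10 of 190 calls (5.3%) had no true change. A simulation with no change gave 1 call among 17293 genes.

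Before the data were examined, 34 gene lists, the tests and the naming rule were fixed. Lists were tested on voom values with camera (limma 3.58.1) at a preset correlation of 0.01, where at least 5 members were tested, which 32 lists met; camera with an estimated correlation and fry stood beside it. The naming rule took the 4 SOWAH family genes, the 12 genes with the largest increase and the 12 with the largest decrease among called genes with a mean of at least 5 CPM and no overlap between groups, and up to 4 members of each list with the smallest adjusted p. Some genes that met this rule are not reported here. FPKM values were tested with limma-trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in at least 3 samples.

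Alternatives were other scaling factors (RLE, upper quartile, library totals alone), other filters, DESeq2 1.42.0, limma-voom, no robust step, a threshold of 0.01, a test against a fold of 1.2, the replicate block, each library left out, and for FPKM a pseudocount of 0.1 and other filters. Added after seeing the data were libraries thinned to the smallest total, genes with an alternate-scaffold copy left out, and genes or list members with 3' UTR matches to the heptamers AGATTTC, GATTTCA, TCGGAGA or CGGAGAA left out.

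For those matches the longest annotated 3' UTR of each gene (GENCODE 29, at least 50 nt) was scanned in Python for 11302 genes with an average log2 CPM of at least 1. These were 88.0% of the genes at that level, and genes with no annotated 3' UTR were not searched. Log2 fold changes, limited to 1 in size, were regressed on the presence of each of 15849 heptamers found in at least 100 genes, with 3' UTR length, base composition and expression as covariates. With fold changes permuted over the same 11302 genes the largest z in size was 4.1, and an implanted heptamer was recovered as the lowest.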

Results

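The data are RNA-seq libraries of SW620, an established human colorectal cancer cell line, taken 72 h after transfection with a small interfering RNA (siRNA). The series is about SOWAHA, a gene of the sosondowah ankyrin repeat family, as a cancer suppressor in metabolic reprogramming. Poly(A) RNA of 3 libraries from cells given a control siRNA (siNC) was compared with that of 3 libraries from cells given an siRNA against SOWAHA (siSOWAHA). Total gene counts were 53281242, 59474396 and 58355125 in siNC replicates 1, 2 and 3, and 49937395, 55082095 and 53662343 in siSOWAHA replicates 1, 2 and 3. No gene took over 1.27% of a library's counts. The labels give no word on whether the libraries of a group came from separate cultures, nor on whether the 3 siSOWAHA libraries received the same siRNA. The p-values therefore measure the spread between these libraries, which may be technical.

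The first comparison asked whether the targeted transcript was lower in the siSOWAHA libraries. SOWAHA (Entrez gene 134548, GRCh38 chromosome 5, 132813302 to 132816786, plus strand) had 32.3, 39.4 and 33.8 normalised counts (CPM, scaled to library size) in the siNC libraries and 7.52, 6.85 and 8.96 CPM in the siSOWAHA libraries. The means were 35.2 ± 3.72 and 7.78 ± 1.08 CPM (SD, n = 3 each), so that 22.1% of the control level was left. The log2 fold change was -2.18 (SE 0.105; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.68e-09). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. In the authors' FPKM values the means were 9.39 ± 0.987 and 2.05 ± 0.288 (SD, n = 3 each). The family members SOWAHB (log2 fold change 0.17, adjusted p = 0.589), SOWAHC (0.19, adjusted p = 0.151) and SOWAHD (-0.44, adjusted p = 0.489) did not pass the edgeR test. The permutation test does not set SOWAHA apart, as it gave p = 0.1 for SOWAHB and SOWAHC too, and p = 0.4 for SOWAHD.

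**Figure D1:**
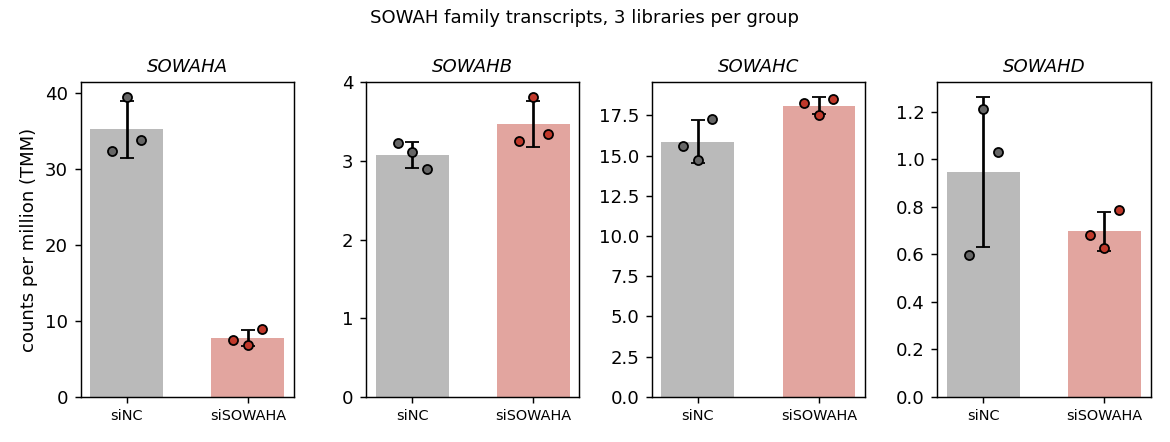
CPM (y axis, a separate scale for each gene) of the 4 SOWAH family genes in the siNC and siSOWAHA libraries. Points are single libraries, bars are means and error bars are SD (n = 3). All 3 siSOWAHA values of SOWAHA, 6.85 to 8.96, lie below the siNC values, 32.3 to 39.4.

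The next comparison covered all genes. SLC44A2, a choline transporter-like protein, rose most among the named genes, from 15.7 ± 1.40 to 55.3 ± 0.997 CPM (log2 fold change 1.81, SE 0.069, adjusted p = 3.46e-10). FXYD2, a regulator of the sodium-potassium pump, rose with a log2 fold change of 1.67 (SE 0.105), and the kinesin KIF19 with 1.5 (SE 0.139). OPRD1, the delta opioid receptor (1.36, SE 0.077), the transcription factor FOXP2 (1.35, SE 0.12) and the aldo-keto reductases AKR1C1 (1.32, SE 0.054) and AKR1C2 (1.1, SE 0.078) followed. RAMP1, a receptor activity-modifying protein, reached 1.15 (SE 0.093), AMBP 1.14 (SE 0.122) and the arrestin-domain protein ARRDC3 1.12 (SE 0.068). GCOM1 was higher by 1.41 (SE 0.337, adjusted p = 0.0309), and this call was lost without siNC replicate 1 (adjusted p = 0.112), siNC replicate 3 (0.128) or siSOWAHA replicate 3 (0.0815). GCOM1 and, among the lower genes, CHKB overlap neighbouring genes, and AKR1C1 and AKR1C2 are near-identical, so their counts are uncertain.

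Apart from SOWAHA, the integrin subunit gene ITGB7 fell most among the named genes, from 13.7 ± 1.85 to 5.64 ± 1.14 CPM (log2 fold change -1.28, SE 0.146, adjusted p = 2.28e-05). The stress-response gene GADD45B fell with a log2 fold change of -1.27 (SE 0.178), the membrane protein gene EMP1 with -1.06 (SE 0.080) and AMOTL2, an angiomotin family gene, with -1.02 (SE 0.096). ULBP1, a ligand of the NKG2D receptor (-0.98, SE 0.12), the ectonucleotidase ENPP1 (-0.95, SE 0.154), the autophagy gene WIPI1 (-0.94, SE 0.152) and EMC2, of the endoplasmic reticulum membrane complex (-0.93, SE 0.080), followed. The keratin KRT15 (-0.92, SE 0.128), the choline kinase CHKB (-0.90, SE 0.122) and GPRC5A (-0.90, SE 0.066) completed the 12 lower genes. Of the 11 lower genes besides SOWAHA, ULBP1, EMC2, EMP1 and GPRC5A carry a match to at least 7 bases of AGATTTCA in the annotated 3' UTR, as did 23.4% of the 8604 genes in the same scan that were not called. SOWAHA itself carries the 7 bases AGATTTC in its 3' UTR. Of the 12 higher genes, FXYD2, OPRD1, AKR1C1 and AKR1C2 also carry a 7-base match to AGATTTCA, and OPRD1 carries one to TCGGAGAA.

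**Figure D2:**
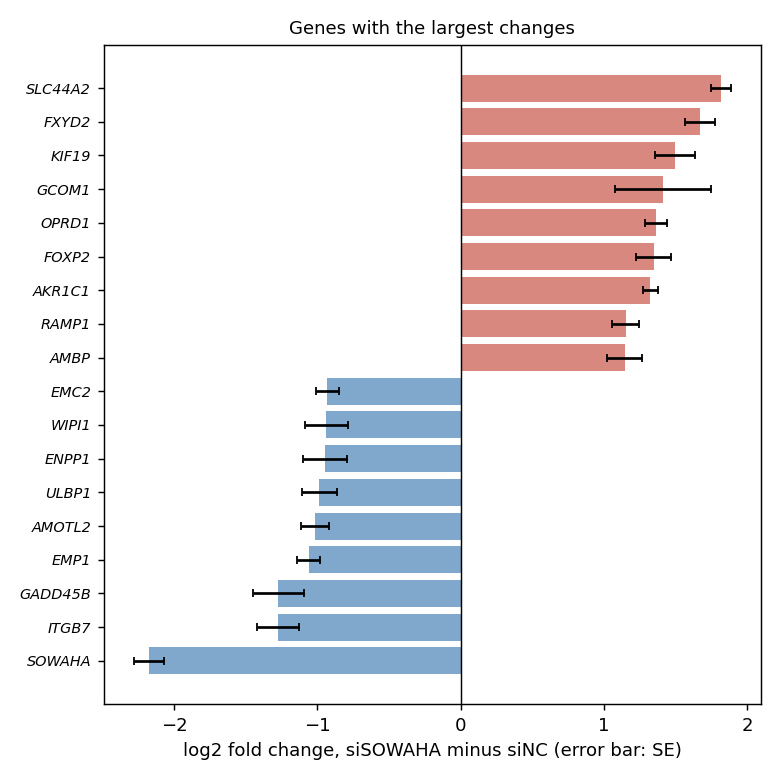
Log2 fold change, siSOWAHA minus siNC (x axis), of the 9 genes with the largest increase and the 9 with the largest decrease that met the naming rule; error bars are SE (n = 3 libraries per group). SOWAHA, at -2.18, has the largest change in size.

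Across the 17693 genes tested, 2988 (16.9%) passed the edgeR quasi-likelihood test, 1614 higher and 1374 lower in the siSOWAHA libraries. Which direction had more genes depended on the scaling, with 1328 higher and 1558 lower with upper-quartile factors and 1323 and 1561 with library totals alone. The changes were small: the called genes had a median absolute log2 fold change of 0.25, a fold of 1.19, and 53 rose and 54 fell by at least 2-fold. With all libraries thinned to 49937395 counts, the number of genes with a count was 20937, 21060 and 21048 in the siNC libraries and 20598, 20771 and 20668 in the siSOWAHA libraries. Of the 2609 long noncoding RNA genes tested, 44 rose and 69 fell. Against a fold of 1.2 as the null, 298 genes were called, and without siNC replicate 3 the number was 1978.

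Of the unfolded protein response list, 13 of 19 tested members were higher and 0 lower (camera adjusted p = 6e-11, and adjusted p = 0.13 with an estimated correlation, which ends the call). The chaperone gene HSPA5 rose from 745 ± 5.63 to 896 ± 12.8 CPM (log2 fold change 0.27), MANF by 0.44 and CALR by 0.23. Adjusted over the list alone, 16 were higher. The NRF2 antioxidant list had 11 of 19 members higher and 2 lower (camera adjusted p = 2.1e-06, and adjusted p = 0.23 with an estimated correlation, which ends the call), including AKR1C1, AKR1C2, AKR1C3 (log2 fold change 0.51) and the peroxiredoxin PRDX1 (0.23); 13 were higher and 2 lower adjusted over the list alone. The 2 lower members, named after their values were seen, were FTH1 (-0.14), a ferritin subunit, and TXNRD1 (-0.12), a thioredoxin reductase. Its members AKR1C1, AKR1C2 and AKR1C3 share near-identical sequence. Of the ATF4 and integrated stress response list, 8 of 20 members were lower and 3 higher (camera adjusted p = 0.018, and adjusted p = 0.23 with an estimated correlation, which ends the call), and 9 and 3 adjusted over the list alone. Among them were the asparagine synthetase ASNS (-0.36) and the tRNA synthetases GARS1 (-0.20) and WARS1 (-0.16). The 3 higher members, named after their values were seen, were NUPR1 (1.51), GDF15 (0.22) and TRIB3 (0.20). Despite the size of its change, NUPR1 is not among the 12 higher genes, because it failed the mean of 5 CPM or the lack of overlap between groups. Leaving members with matches to AGATTTCA or TCGGAGAA out of the ATF4 list gave adjusted p = 0.0503.

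Of the NF-kB and inflammatory list, 11 of 20 tested members were higher and 0 lower (camera adjusted p = 3.9e-08, and adjusted p = 0.13 with an estimated correlation, which ends the call), and 12 higher adjusted over the list alone. The chemokine genes CXCL1 (log2 fold change 0.86, SE 0.063), CXCL8 (0.85, SE 0.067) and CXCL3 (0.92, SE 0.103) and the mitochondrial superoxide dismutase SOD2 (0.42, SE 0.036) were among them. Of the interferon-stimulated genes, 0 of 21 were higher and 2 lower, OAS2 (-0.65) and OAS1 (-0.34), and the list was not called by camera (adjusted p = 0.095) but was called, as lower, by fry (adjusted p = 0.02), a test of the list on its own.

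Of the 30 G2/M and mitosis genes, 0 were higher and 17 lower (camera adjusted p = 2.8e-09, and adjusted p = 0.23 with an estimated correlation, which ends the call), and 21 were lower adjusted over the list alone. The mitotic kinesins KIF20A and KIF23 fell by 0.34 and 0.32 on the log2 scale, DLGAP5 by 0.29 and cyclin B2, CCNB2, by 0.26. Of the 30 G1/S and DNA replication genes, 5 were higher and 1 lower (camera adjusted p = 0.023, and adjusted p = 0.28 with an estimated correlation, which ends the call), and 7 and 1 adjusted over the list alone, with CDC6 at 0.27, FEN1 at 0.17 and MCM3 at 0.14. The G1/S call was lost without siSOWAHA replicate 2 (adjusted p = 0.0527). Replication-dependent histones (1 higher, 1 lower of 15, adjusted p = 0.48) and p53 targets (4 higher, 3 lower of 20, adjusted p = 0.72) were not called by camera or fry. Among the p53 targets, ZMAT3 fell (-0.71) and CCNG1 rose (0.45), and the list's median (-0.004) and mean (-0.054) were below 0 while camera gave the direction up. ZMAT3 carries AGATTTCA in its 3' UTR, and CCNG1 has no match to AGATTTCA or TCGGAGAA there.

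Of 46 nuclear-encoded oxidative phosphorylation genes, 7 were higher and 1 lower (camera adjusted p = 0.048, and adjusted p = 0.65 with an estimated correlation, which ends the call). The list was not called by fry (adjusted p = 0.31), nor by camera with library totals alone (0.11), with a filter of 1 CPM (0.0813), without siNC replicate 3 (0.206) or without siSOWAHA replicate 2 (0.388). ATP5PB, of ATP synthase, rose by a log2 fold change of 0.19. The glutamine and amino acid list had 8 of 22 members higher and 2 lower (camera adjusted p = 0.031, and adjusted p = 0.35 with an estimated correlation, which ends the call), with the ornithine decarboxylase ODC1 at 0.29 and the transporter SLC7A5 at -0.27; it was not called without siNC replicate 3 (0.0657) or siSOWAHA replicate 2 (0.0624). Nucleotide synthesis had 6 of 19 higher and 1 lower (camera adjusted p = 0.016, and adjusted p = 0.35 with an estimated correlation, which ends the call). Its adjusted p was 0.0527 without siSOWAHA replicate 2. Its member PAICS, a purine synthesis enzyme, rose by 0.13 and was not called without siNC replicate 3 (0.07) or siSOWAHA replicate 2 (0.0506). Adjusted over the list alone, the numbers higher and lower were 8 and 1 for oxidative phosphorylation, 9 and 3 for glutamine and 7 and 1 for nucleotide synthesis.

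The remaining metabolic lists were not called by camera with the preset correlation. Fry called 4 of them as lower: glycolysis (adjusted p = 0.02), serine and one-carbon metabolism (0.0018), hypoxia-induced genes (0.038) and cholesterol synthesis (0.04). Of 24 glycolysis genes, 2 were higher and 7 lower (camera adjusted p = 0.088), and 4 and 9 adjusted over the list alone. The glucose transporters SLC2A3 and SLC2A1 fell by 0.86 and 0.45 on the log2 scale and PFKFB4 by 0.45, while PFKM rose by 0.28. The list was called by camera with library totals alone (adjusted p = 0.0304) and without siSOWAHA replicate 2 (0.0299). In serine and one-carbon metabolism, 1 of 16 was higher and 6 lower (adjusted p = 0.07), including PSAT1 (-0.56), PSPH (-0.50) and SLC1A4 (-0.72). Camera called it with library totals alone (0.0489), with a filter of 1 CPM (0.042), without siNC replicate 1 (0.0323) and without siSOWAHA replicate 2 (0.0443). In the 3' UTR, PSAT1 carries AGATTTCA, SLC1A4 a 7-base match to it and PSPH only its middle 6 bases. Matches of at least 7 bases were in 32.3% of called lower, 24.4% of called higher and 23.4% of uncalled genes in the scan. Hypoxia-induced genes had 2 of 19 higher and 4 lower (adjusted p = 0.17), including NDRG1 (-0.61). The TCA cycle had 3 of 25 higher and 2 lower (adjusted p = 0.48), with IDH1 at -0.30, and the pentose phosphate pathway had 3 of 11 higher and 2 lower (adjusted p = 0.48), with TKT at 0.27. Cholesterol synthesis (2 higher, 3 lower of 25, adjusted p = 0.24), fatty acid synthesis (2 higher, 4 lower of 23, adjusted p = 0.48) and fatty acid oxidation (1 higher, 2 lower of 22, adjusted p = 0.72) were not called by camera. In the fatty acid synthesis list the malic enzyme ME1, whose 3' UTR carries a 7-base match to TCGGAGAA, rose by 0.59. None of the 13 mitochondrially encoded protein-coding genes was in the count table.

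Ribosome biogenesis genes had 9 of 26 members higher and 1 lower (camera adjusted p = 0.00052, and adjusted p = 0.13 with an estimated correlation, which ends the call). NOLC1 rose from 324 ± 8.31 to 546 ± 3.35 CPM (log2 fold change 0.76, edgeR adjusted p = 3.46e-10). Its 3' UTR carries a 7-base match to TCGGAGAA. Matches of at least 7 bases were in 3.6% of the scanned genes that were not called. Of 44 cytosolic ribosomal proteins, 8 were higher and 0 lower (camera adjusted p = 6.7e-05, and adjusted p = 0.61 with an estimated correlation, which ends the call), and fry did not call the list (adjusted p = 0.29). RPLP2 and RPL24 were at 0.13 and 0.18. These genes have many processed copies in the genome, so their counts are uncertain. Lysosome and autophagy genes had 8 of 25 higher and 2 lower (camera adjusted p = 0.021, and adjusted p = 0.23 with an estimated correlation, which ends the call), including ATP6V0D1 (0.29) and WIPI1 (-0.94). Adjusted over the list alone, the numbers higher and lower were 9 and 2 for ribosome biogenesis, 10 and 0 for ribosomal proteins and 10 and 2 for lysosome genes.

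Epithelial markers had 0 of 25 higher and 6 lower (camera adjusted p = 0.0035, and adjusted p = 0.16 with an estimated correlation, which ends the call), with the keratins KRT19 (-0.30) and KRT8 (-0.12). Intestinal differentiation markers had 0 of 17 higher and 4 lower (camera adjusted p = 0.043, and adjusted p = 0.33 with an estimated correlation, which ends the call), with the cadherin CDH17 (-0.59), the transcription factor CDX2 (-0.43), CEACAM1 (-0.40) and TFF3 (-0.29). The intestinal call was also lost without siNC replicate 1 (adjusted p = 0.0533), without siSOWAHA replicate 2 (0.0822) and with members carrying the AGATTTCA or TCGGAGAA matches left out (0.225). Adjusted over the list alone, 10 epithelial and 4 intestinal genes were lower. Mesenchymal markers (3 higher, 3 lower of 13) were not called by camera (adjusted p = 0.89) or fry (adjusted p = 0.78). Their direction was up by camera and median and down by fry. Wnt targets had 7 of 24 higher and 5 lower (adjusted p = 0.72). Among them cyclin D1, CCND1, fell from 194 ± 2.72 to 107 ± 5.23 CPM (log2 fold change -0.86, SE 0.040, adjusted p = 2.6e-09) and AXIN2 fell (-0.36), while SMOC2 rose (0.67). YAP/TAZ targets had 3 of 15 higher and 5 lower (camera adjusted p = 0.28, and fry adjusted p = 0.044), including AMOTL2 and GADD45B. Immediate-early genes (4 higher, 3 lower of 22, adjusted p = 0.19) included MYC at 0.22, and small-RNA pathway genes (2 higher, 1 lower of 13, adjusted p = 0.49) included DROSHA at 0.23.

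**Figure D3:**
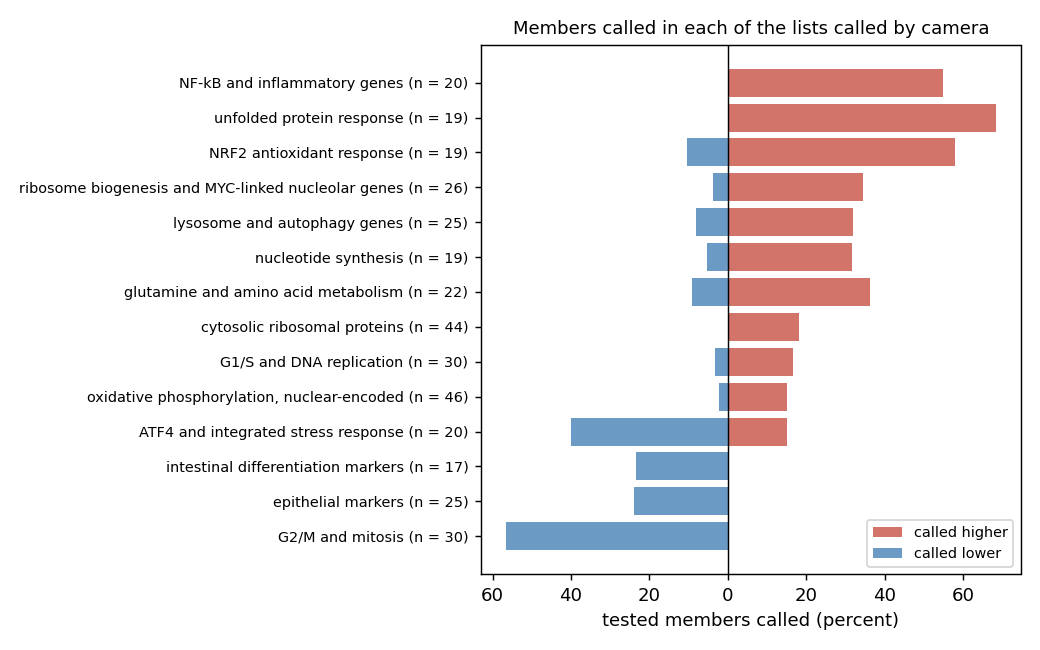
Percent of tested members (x axis) called higher (right) or lower (left) in siSOWAHA, edgeR adjusted p under 0.05, for the 14 lists called by camera with a preset correlation, of which 0 were called with an estimated correlation. The unfolded protein response list has 13 of 19 members higher and 0 lower, and the G2/M list 17 of 30 lower and 0 higher.

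Markers of other cell types were not called as lists by camera or fry. Of 7 fibroblast markers tested, 1 was higher, LUM, from 61.1 ± 2.19 to 76.4 ± 5.15 CPM (camera adjusted p = 0.9 for the list, whose direction was down by camera and up by fry). Of 5 leukocyte markers 0 were called (adjusted p = 0.48), with LYZ at 7.39 and 6.69 CPM, and of 3 endothelial markers 0, too few for a list test, with VWF at 1.21 and 1.31 CPM. Over all lists, 14 of 32 were called by camera with a preset correlation, 0 with a correlation estimated from these libraries, where 6 had an unadjusted p under 0.05, and 18 by fry.

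The same comparison was made in the authors' FPKM values with limma on log2(FPKM + 1). Of 12027 genes tested, 2494 passed, 1149 higher and 1345 lower. Of the 11965 genes tested in both tables, 2232 were called in both and all of these had the same direction, against 581.5 by chance for independent lists. Both tables come from the same reads, so this compares the values and tests only. SOWAHA fell by 1.77 on the log2(FPKM + 1) scale (adjusted p = 9.01e-06), which understates changes of low genes. The number of calls was 1639 without siNC replicate 1, 1579 without siNC replicate 3, 1636 without siSOWAHA replicate 3 and 1369 with no filter on low values.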

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

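The heptamer, thinning and alternate-scaffold settings were chosen after seeing the data; all others were fixed before the data were examined. SOWAHA kept its direction and call in all 15 alternatives, with log2 fold changes of -2.29 to -2.09. The count of 2988 changed genes fell to 1556 at an adjusted p under 0.01 and to 298 against a fold of 1.2, both stricter by construction, and ranged from 1978 to 2678 with a library left out, where fewer samples are tested. Leaving out the 3439 tested genes with a heptamer match gave 2117, thinning 2926 and leaving out alternate-scaffold genes 2885. With library totals alone 45.9% of 2884 calls were higher, and with upper-quartile factors 1328 of 2886, against 54% with TMM. Deviations of same-numbered libraries from their group means had correlations of -0.233, 0.003 and -0.035, and no library correlated best with its own number; the replicate block gave 2599 genes, 14 lists and 2062 genes in the FPKM values. The 14 called lists became 0 with an estimated correlation, and ranged from 11 to 14 with a library left out. The estimated correlation was below the preset 0.01 for epithelial markers (-0.0075), ribosome biogenesis (-0.0081) and lysosome genes (-0.033), which lost their calls too. For these lists this argues against a higher correlation as the cause. For epithelial markers the unadjusted camera p rose from 0.000761 to 0.02 at the lower correlation. The setting therefore changed more than the correlation, and a call lost under it is not by itself a sign of correlated genes. The cause was not otherwise tested. The 2494 genes called in the FPKM values became 1369 with no filter, the cause of which was not tested, and 1579 to 2163 with a library left out. Of 140 named genes, 115 kept their call, or stayed uncalled, in all alternatives run, and the others lost their call in at least 1 but kept direction. Across alternatives 5 uncalled named-gene values and 13 uncalled list directions changed sign. Depth limits SOWAHD, at 0.947 and 0.698 CPM.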

Other observations

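The pathway tests, the gene LTB and the heptamer tests by site type in held-out genes, coding sequence, base composition and library splits were chosen only after the result was seen; the tests by number of sites, GC content and length, depth and the splits of gene and list counts were fixed before theirs. With the pathway annotation in the authors' table, 7 of 326 KEGG pathways with at least 10 tested genes were called by camera, all higher, and 0 with an estimated correlation. The 7, each with adjusted p = 0.85 with an estimated correlation, were Ribosome, with 22 of 130 genes higher and 2 lower (adjusted p = 4.4e-05), Legionellosis, with 18 of 47 and 1 (0.0017), and protein processing in the endoplasmic reticulum, with 42 of 157 and 7 (0.0022). The others were antigen processing and presentation, with 15 of 49 and 1 (0.0034), IL-17 signaling, with 16 of 62 and 3 (0.03), ribosome biogenesis, with 15 of 75 and 4 (0.031), and thyroid hormone synthesis, with 12 of 48 and 1 (0.044). Among the pathways not called, NF-kappa B signaling had 16 of 76 higher and 6 lower (adjusted p = 0.7), oxidative phosphorylation 14 of 110 and 4 (0.24), lysosome 17 of 119 and 11 (0.46) and cell cycle 19 of 120 and 16 (0.89). Below the 5 CPM of the naming rule, the lymphotoxin gene LTB rose from 1.69 ± 0.429 to 4.02 ± 0.341 CPM (SD, n = 3 each; edgeR adjusted p = 0.000825), a fold of 2.38.

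Genes with AGATTTC in the 3' UTR (1851 genes) were lower in siSOWAHA than other genes, by 0.053 on the log2 scale (z = -9.24), the lowest of 15849 heptamers. Apart from GATTTCA, which overlaps it and had a z of -8.73, the lowest z among 418 other heptamers of the same bases was -2.88, which argues against base composition as the cause. A candidate explanation is that a strand of the siRNA in the siSOWAHA libraries paired with these sites through its seed, the bases near its 5' end. With the site picked in 1 set of genes and measured in the other, both sets gave AGATTTCA. Genes with these 8 bases differed from genes with the 6-base core by -0.062 (SE 0.015) and -0.070 (SE 0.015). Over all 11302 genes, those used to pick the site included, genes with 2 or more sites differed from genes with 1 by -0.041 (SE 0.009). In genes with no 3' UTR core, those with AGATTTCA in the coding sequence were shifted by -0.036 (SE 0.013, 286 genes). The SOWAHA transcript has AGATTTC 1 time, as 21.7% of transcripts of similar length have it at least 1 time, and the 8 bases AGATTTCA 0 times. Of the 10 splits of the 6 libraries the real one (1) had the largest z in size, 9.27 against at most 6.34. Every other split mixes the groups unevenly and keeps part of the group difference, so 6.34 is no chance level. The 10 splits are also too few for a share under 0.05. SOWAHA loss stays open as an untested source of changes.

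Genes with CGGAGAA in the 3' UTR (305 genes) were higher in siSOWAHA, by 0.094 on the log2 scale (z = 7.67), the highest of all heptamers. Among 139 other heptamers of the same bases the highest z was 3.02, which argues against base composition. Seed pairing of a control siRNA strand, which would lower these genes in the siNC libraries, stays open. With the site picked in 1 set of genes and measured in the other, 1 set gave TCGGAGAA. Its genes lay above those with the 6-base core by 0.193 (SE 0.038). The other set gave CCGGAGAA, with a difference of 0.025 (SE 0.035), so the sets tested different 8-base sites. The heptamers picked in each set, TCGGAGA and CGGAGAA, had shifts of 0.071 (z = 3.73) and 0.068 (z = 3.93) in the genes not used to pick them. In genes with no 3' UTR core, those with TCGGAGAA in the coding sequence were higher by 0.077 (SE 0.013, 262 genes). Of 1492 called higher genes in the scan 8.0% had a match of at least 7 bases to TCGGAGAA, against 3.6% of genes not called, and of 1206 called lower genes 32.3% had one to AGATTTCA, against 23.4%. The heptamers were picked from the fold changes of these same genes, so the shares are no separate test. Of the 10 splits the real one (1) had the largest z in size, 7.72 against at most 6.68. Here too the other splits keep part of the group difference, so 6.68 is no chance level, and 10 splits are too few for a share under 0.05.

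The many small changes were weighed last. After a per-library correction for transcript GC content and length, 3293 genes were called, against 3079 in the same fit without it and with 2851 in both, which argues against these trends as the whole cause. With all libraries thinned to 49937395 counts, 2926 were called, which argues against unequal depth between the libraries as the cause. Before thinning the totals were 49937395 to 59474396, so little was removed, and the effect of a much lower depth was not tested. Of the 10 splits only the real one (1) gave as many genes, 2988 against at most 1, as many lists, 14 against at most 6, and as many genes in the FPKM values, 2494 against at most 0, but the splits are too few for a share under 0.05. Every other split mixes the groups, so the group difference adds to its within-group spread and few gene calls would follow whatever the cause. Several of these splits still called 4 to 6 lists, so camera with the preset correlation called lists where at most 1 gene was called. Because these splits keep part of the group difference, this gives no rate of false list calls. A biological effect of SOWAHA loss, a response to either siRNA and differences between cultures or plates stay open, since a single targeting siRNA group and no rescue were compared.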
